A study of Mus musculus with 8 samples.

How the data were processed

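RNA-seq of interscapular brown adipose tissue from 4 control and 4 Hdac3 knockout libraries was analysed from 1 deposited table of 11234 genes. Per the submitters' processing notes, the authors used TopHat2, featureCounts and edgeR with the mouse build mm9. Versions, settings, the annotation, the strand setting and the gene filter are not given in the sources used here. Per the file headers, the authors deposited RPKM per library, a log2 fold change, an average log2 CPM, a p-value and an FDR per gene. The deposited log2 fold change is positive where the RPKM values are higher in the knockout. The deposited FDR equals a Benjamini-Hochberg adjustment of the deposited p-value over the listed genes.

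The deposited RPKM values are whole reads divided by gene length and a library total. Whole reads were recovered for 100% of values within a tolerance of 0.001 reads, after 44 genes were corrected for a factor shared by all libraries. Library totals implied by the values were 13619308 to 17986134 reads, and reads on listed genes 2738477 to 4170691. At these totals 1 read on a gene model of 1 kb is worth 0.0556 to 0.0734 RPKM. PCR duplicates cannot be removed from such values, so read numbers state counting error at best. All per-sample columns belong to the 8 libraries.

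The plan fixed before the data were examined assumed a table of counts and a count test. For a table of RPKM it named limma with a trend on log2(value + 1) over genes with a mean of at least 1. As an added alternative it named the count test on recovered whole reads, in place of which limma voom was run. It did not say whether a composition factor applied to RPKM. TMM factors (trim 0.3 of log ratios and 0.05 of mean levels), the normalization named in the plan, were kept for the main result; this reading was settled after the table had been opened. The plain library total is the alternative, and its effect is large. Main results are therefore from limma 3.58.1 in R 4.3.3 on log2(TMM-scaled RPKM + 1) of 8764 genes with a mean of at least 1 RPKM. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. Group means and SD are of TMM-scaled RPKM, and folds without a library keep the factors of the full set. These folds were computed after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

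Lists of genes for 32 pathways, complexes and cell types were fixed before the data were examined, and the 29 with at least 3 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists). Named genes followed a rule fixed at the same time. They are Hdac3, Ucp1, Ppargc1a, Esrra and Dio2 whatever their values. To these come the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 RPKM and genotypes that do not overlap, without predicted or unnamed transcripts, microRNA, small nucleolar and ribosomal RNA. From each list up to 4 members with the smallest adjusted p were taken. Pfkp lies outside the rule and was added after its values were seen. Hdac3 was also tested by an exact permutation over 70 splits.

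Alternatives were RLE size factors, the library total alone, no filter, CPM above 1 in at least 4 libraries, a pseudocount of 0.1, limma voom on recovered reads, a log2 fold change of at least 1, camera with an estimated correlation, fry, lists without shared members, and leaving out each library. The sum of reads on listed genes as library size was added after seeing the data. The method was tested on simulated counts of the same genes and library sizes with a dispersion of 0.05. Of 8753 genes tested there, it called 10.4% of 67 genes changed 1.5-fold, 57.1% of 63 changed 2-fold and 100% of 59 changed 4-fold, and 0.13% of 8528 unchanged genes. The simulated genes vary independently, unlike the measured ones. Their dispersion was set, not estimated from these libraries, and far fewer of them were changed than were called in the measured data. The rates hold for that setting only, and an uneven shift of many genes, which bears on scaling, was not simulated.

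GC content was taken from GENCODE M21 transcripts of the later build GRCm38, matched by symbol or alias for 99.29% of listed genes. Because that build differs from mm9, no coordinates are given. Genes with near-identical copies (Cyp, Ces1, H2, histone and metallothionein families) and overlapping or antisense genes are uncertain, since the treatment of shared reads is not given in the sources used here.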

Results

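Interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades, was taken from male C57BL/6 mice at 12 weeks of age. The animals had spent 2 weeks at 29 °C, close to the temperature at which a mouse spends no extra energy on keeping warm, and were killed at 5 PM, 10 h after lights on (zeitgeber time 10). Total RNA depleted of ribosomal RNA was sequenced in 8 libraries. The 4 control libraries (replicates 11, 12, 13 and 14) carry a loxP-flanked Hdac3 gene, and the 4 knockout libraries (replicates 4, 5, 19 and 20) carry in addition a Cre recombinase driven by the adiponectin promoter, which is active in adipocytes. HDAC3 is a histone deacetylase that works with the NCoR and SMRT corepressors. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries. The authors' table lists 11234 genes as RPKM. The values imply library totals of 13619308 to 17986134 reads, of which 2738477 to 4170691 fell on the listed genes. The share on listed genes was 18.3% ± 1.28 (SD, n = 4) in control and 23.2% ± 1.46 (SD, n = 4) in knockout libraries, with every knockout library above every control library (exact permutation test, two-sided p = 0.0286, the smallest the design allows).

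The targeted gene was examined first. Hdac3 stood at 7.64 ± 0.511 RPKM in control and 3.29 ± 0.588 RPKM in knockout libraries (SD, n = 4 each), so that the knockout mean was 43.0% of the control mean. The 4 knockout libraries held 98, 129, 129 and 114 reads of the gene and the 4 control libraries 208, 254, 223 and 246. All knockout libraries lay below all control libraries (exact permutation test, two-sided p = 0.0286; limma, adjusted p = 4.33e-05). In the authors' deposited table the log2 fold change of Hdac3 was -1.24. Dissected fat also holds cells that are not adipocytes, and a value per gene does not separate the floxed exons from the rest. The first principal component of the log2 values held 63.6% of the variance and parted the genotypes. Pearson correlations across genes were 0.980 to 0.988 within a genotype and at most 0.953 between genotypes.

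The main comparison asked which transcripts of brown fat at thermoneutrality differed when Hdac3 was deleted in adipocytes. Ucp1, the uncoupling protein that lets brown-fat mitochondria release energy as heat, showed the largest fall of all named genes, from 158.9 ± 40.3 to 4.01 ± 2.90 RPKM (SD, n = 4 each), a 39.6-fold lower mean. This fold rests in part on knockout replicate 19, at 8.26 RPKM against 2.02 to 3.45 RPKM in the other knockout libraries; it was 61.2-fold without that library and 34.0-fold to 43.1-fold without any other. Ppargc1a, a coactivator of mitochondrial genes, fell from 2.21 ± 0.401 to 0.977 ± 0.161 RPKM. Esrra, a nuclear receptor that acts on the same genes, stood at 11.7 ± 1.55 and 12.7 ± 1.57 RPKM and did not pass the test (limma, adjusted p = 0.448). Dio2 is not among the listed genes and was not analysed here. Of 8764 genes tested, 1703 were higher and 1391 lower in the knockout (limma on log2(RPKM + 1), Benjamini-Hochberg, threshold 0.05). The split depends on scaling. With the library total alone it was 2796 higher and 628 lower. With the sum of reads on listed genes as library size, chosen after the data were seen, it was 1087 and 2651. The median log2 fold change moved by 0.14 and -0.12 under these 2 scalings, and the changes below are relative to the TMM scaling. The authors' deposited table, with FDR below 0.05 over all its genes, gives 1911 higher and 1860 lower.

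**Figure D1:**
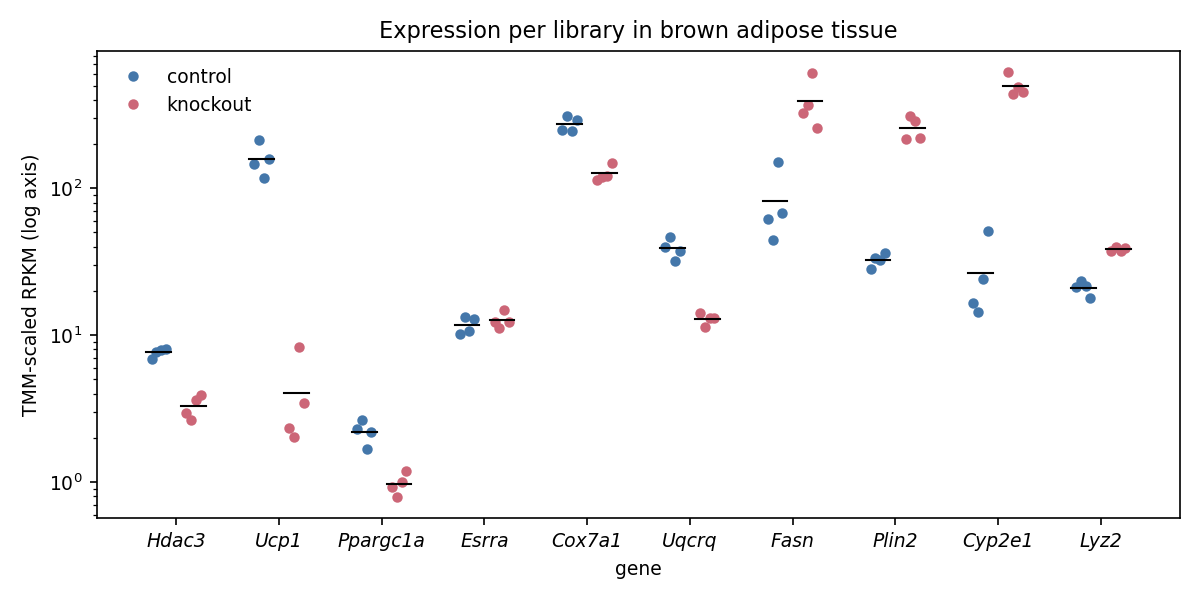
Expression of 10 genes in each of the 8 libraries as TMM-scaled RPKM on a log axis, with control libraries in blue, knockout libraries in red and the group mean as a black bar. Hdac3 ranged around 7.64 in control and 3.29 in knockout libraries, and Ucp1 around 158.9 and 4.01.

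The largest falls after Ucp1 included Tusc3, a magnesium transport and glycosylation factor, which stood at 28.4 ± 7.68 RPKM in control and 2.40 ± 0.412 RPKM in knockout libraries. Nnat fell from 17.5 ± 5.54 to 2.38 ± 0.359 RPKM and Kng2, a kininogen, from 15.3 ± 2.16 to 2.43 ± 1.08 RPKM. Ckb, the brain-type creatine kinase, fell from 25.8 ± 8.31 to 5.73 ± 0.851 RPKM, and Pm20d1, a secreted enzyme that makes N-acyl amino acids, fell from 4.47 ± 0.524 to 0.456 ± 0.0989 RPKM. Lctl, Gmpr, Ccdc3 and Ak1 completed the 10 largest falls. Falls and rises are ranked on the log2(RPKM + 1) scale, on which low genes count for less. The largest rise on that scale was that of Cyp2e1, a cytochrome P450 that oxidises small organic molecules, 18.9-fold from 26.5 ± 17.0 to 500.4 ± 81.5 RPKM, or 27.4-fold without control replicate 14, which held 51.2 RPKM. Plin2, a coat protein of lipid droplets, rose from 32.6 ± 3.49 to 259 ± 47.0 RPKM. Slc25a34, a mitochondrial carrier, rose 27.8-fold from 0.288 ± 0.138 to 8.0 ± 0.632 RPKM, and Ehhadh, an enzyme of peroxisomal fatty acid oxidation, from 2.73 ± 0.727 to 26.4 ± 12.2 RPKM. Mt2, Cmbl, Tst, Fasn, Ces1f and Agpat2 completed the 10 largest rises. Errors are SD with n = 4 in each genotype. By the rule that picked them, each of these genes passed the threshold and had all 4 libraries of one genotype above all 4 of the other. Their limma adjusted p was at most 0.000684. Over all genes tested, 3048 of 8764 had genotypes that did not overlap, where chance gives 2.86%.

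Nuclear-encoded transcripts of the respiratory chain and the tricarboxylic acid cycle were lower in the knockout. Of 36 subunits of complex I, 26 fell and none rose, or 27 adjusted over the list alone. Examples were Ndufb2, from 45.6 ± 3.505 to 22.7 ± 1.48 RPKM, and Ndufab1, from 31.2 ± 2.43 to 15.7 ± 1.99 RPKM. Of 14 genes of complexes II and III, 11 fell, with 11 adjusted over the list alone; Uqcrq, a complex III subunit, went from 39.0 ± 5.93 to 12.9 ± 1.13 RPKM. In complex IV, 11 of 17 fell and 1 rose, with 12 lower and 1 higher adjusted over the list alone. Cox7a1, which forms part of complex IV in muscle and brown fat, fell from 274.1 ± 31.7 to 126 ± 14.9 RPKM. In ATP synthase, 10 of 16 fell and 1 rose, the same counts as those adjusted over the list alone. The member that rose was Atp5g1, a subunit of the membrane ring, from 1.94 ± 0.492 to 6.67 ± 0.312 RPKM. In the tricarboxylic acid cycle, 13 of 22 fell and 1 rose, with 14 and 1 adjusted over the list alone. Fh1, fumarate hydratase, fell from 101.9 ± 9.45 to 56.9 ± 4.83 RPKM, while Pcx, pyruvate carboxylase, rose from 40.1 ± 4.28 to 83.5 ± 14.1 RPKM. Errors are SD with n = 4. The median log2 fold changes of these 5 lists lay between -0.48 and -0.30. Their camera adjusted p-values with the preset correlation were 2.93e-09 for complex I, 2.44e-05 for complexes II and III, 1.50e-05 for complex IV, 0.00221 for ATP synthase and 1.46e-05 for the tricarboxylic acid cycle. With an estimated correlation none passed (adjusted p = 0.515 for ATP synthase and adjusted p = 0.451 for the other 4). With the library total alone 43 of the 101 genes in these lists fell and 10 rose, against 68 and 3 under TMM.

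Other mitochondrial and thermogenic lists had no direction that held under every scaling, or held members that rose beside members that fell. In mitochondrial fatty acid oxidation, 3 of 22 rose and 5 fell, with the same counts adjusted over the list alone. Cpt2, which releases acyl groups inside mitochondria, rose from 31.1 ± 2.04 to 59.2 ± 1.99 RPKM, and Acaa2, a thiolase, fell from 407.7 ± 47.4 to 246.8 ± 33.8 RPKM. In the mitochondrial ribosome, 12 of 77 rose and 15 fell, with 12 and 17 adjusted over the list alone. In the brown thermogenic programme, 3 of 14 rose and 7 fell, with the same counts adjusted over the list alone. This list did not pass with camera (adjusted p = 0.0918, and adjusted p = 0.515 with an estimated correlation) but was called lower by fry (adjusted p = 0.0104). Its members that rose included Adrb3, the adrenergic receptor of adipocytes, from 4.10 ± 0.905 to 12.5 ± 3.48 RPKM. In glucose uptake and glycolysis, 2 of 19 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0503). Pfkm and Pfkl, forms of phosphofructokinase, fell from 12.2 ± 0.436 to 6.35 ± 0.404 RPKM and from 24.6 ± 2.29 to 12.0 ± 0.860 RPKM, while the remaining form, Pfkp, named after its values were seen, rose from 3.65 ± 0.537 to 5.33 ± 0.226 RPKM (limma, adjusted p = 0.00234). In branched-chain amino acid catabolism, 4 of 20 rose and 6 fell, with 7 and 6 adjusted over the list alone. In creatine and calcium cycling, 2 of 5 fell, with 2 lower and 1 higher adjusted over the list alone. Among nuclear receptors and mitochondrial regulators, 4 of 16 rose and 4 fell, with the same counts adjusted over the list alone. The balance depends on the scaling in 5 of these lists. With the library total alone, 11 genes rose and 5 fell in mitochondrial fatty acid oxidation, 17 and 4 in the mitochondrial ribosome, 11 and 4 in branched-chain amino acid catabolism, 1 and 1 in creatine and calcium cycling and 7 and 2 among nuclear receptors. With the listed-gene sum, in the same order, 2 rose and 6 fell, 5 and 30, 1 and 9, 0 and 2, and 2 and 7. The brown thermogenic programme (3 higher and 5 lower, then 2 and 7) and glucose uptake and glycolysis (2 and 4, then 2 and 9) kept more falls than rises under both. Median and mean differed in sign in fatty acid oxidation, branched-chain amino acid catabolism, creatine and calcium cycling and nuclear receptors, none of which passed. Nrip1, a corepressor, rose from 2.02 ± 0.260 to 4.76 ± 0.290 RPKM and Perm1, a regulator of oxidative genes, fell from 5.54 ± 0.956 to 1.84 ± 0.449 RPKM. Errors are SD with n = 4.

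Genes of lipid synthesis and storage were higher in the knockout. Of 23 genes of lipid synthesis, 19 rose and 1 fell, with the same counts adjusted over the list alone. Fasn, fatty acid synthase, rose from 81.3 ± 47.5 to 390.8 ± 151 RPKM, and Srebf1, a transcription factor of lipid synthesis, from 18.2 ± 3.54 to 61.8 ± 8.02 RPKM. Elovl5, a fatty acid elongase, rose from 5.60 ± 0.255 to 17.6 ± 2.38 RPKM. Of 21 genes of lipid uptake, storage and lipolysis, 13 rose and none fell, with 13 higher and 1 lower adjusted over the list alone. Lpl, lipoprotein lipase, rose from 140.5 ± 5.72 to 370.4 ± 47.2 RPKM and Cidec, which enlarges lipid droplets, from 104.3 ± 15.6 to 398.7 ± 51.4 RPKM. Of 14 adipocyte identity genes, several shared with the lipid lists, 9 rose and none fell, with 9 adjusted over the list alone. Fabp4, a fatty acid carrier, rose from 1698 ± 59.8 to 3985 ± 392.9 RPKM. Errors are SD with n = 4. The median log2 fold changes were 0.79, 0.61 and 0.44. The camera adjusted p-values with the preset correlation were 1.55e-07, 1.36e-05 and 0.000384, and none passed with an estimated correlation (adjusted p = 0.421, adjusted p = 0.421 and adjusted p = 0.451).

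Macrophage markers were higher, as were the adipocyte identity genes, while no list of the other cell types compared passed the camera test. Of 14 macrophage markers tested, 12 rose and none fell, with 12 adjusted over the list alone (median log2 fold change 0.69, camera adjusted p = 1.36e-05; adjusted p = 0.421 with an estimated correlation). Lyz2, lysozyme, rose from 21.1 ± 2.32 to 38.3 ± 1.21 RPKM and C1qa, a complement component, from 5.53 ± 1.03 to 10.97 ± 2.00 RPKM. None of 13 endothelial markers rose and 2 fell, with 1 lower adjusted over the list alone. Of 15 fibroblast and matrix markers 2 rose, with 1 adjusted over the list alone, among them Dpt from 7.68 ± 1.63 to 23.8 ± 5.25 RPKM. Of 8 smooth muscle and pericyte markers 1 fell, with 1 adjusted over the list alone, and this was Des, desmin, from 5.66 ± 0.938 to 1.78 ± 0.127 RPKM. No skeletal muscle (3 tested) or erythroid (5 tested) marker passed. Of 3 nerve and Schwann cell markers, S100b alone fell, from 8.70 ± 2.07 to 2.10 ± 0.470 RPKM, with 1 adjusted over the list alone. Among 6 white adipocyte markers, 1 rose and 2 fell, with 1 higher and 3 lower adjusted over the list alone, and their median was below and their mean above 0. With the library total alone 1 endothelial marker rose and none fell, 2 white adipocyte markers rose and 1 fell, and 3 fibroblast markers rose. With the listed-gene sum 6 endothelial markers fell, 1 white adipocyte marker rose and 3 fell, 1 fibroblast marker rose and 3 smooth muscle markers fell. Lymphocyte markers and the mitochondrial DNA-encoded genes had no gene that could be tested, and cell cycle genes had 2, so these lists were not tested. Errors are SD with n = 4.

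Stress, interferon, clock and corepressor genes were also compared. Of 16 oxidative stress genes, 11 rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 0.000107; adjusted p = 0.421 with an estimated correlation). Gsr, glutathione reductase, rose from 1.96 ± 0.146 to 3.97 ± 0.0712 RPKM and Cat, catalase, from 47.8 ± 3.22 to 81.3 ± 5.28 RPKM. Of 11 interferon response genes 7 rose, with 8 adjusted over the list alone (camera adjusted p = 0.00133; adjusted p = 0.451 with an estimated correlation). Usp18, which limits interferon signalling, rose from 1.54 ± 0.245 to 5.78 ± 1.09 RPKM. Macrophage markers rose in the same libraries. Of 16 circadian clock genes 8 rose and 1 fell, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.421 with an estimated correlation). Nr1d1, which encodes a clock repressor that recruits NCoR and HDAC3, rose from 13.3 ± 2.46 to 20.9 ± 2.29 RPKM. Among other histone deacetylases and NCoR/SMRT complex genes, 6 of 12 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0918; adjusted p = 0.421 with an estimated correlation), against 6 and 1 with the library total alone and 3 and 1 with the listed-gene sum. Tbl1xr1 and Tbl1x, subunits of the corepressor complex, rose from 1.77 ± 0.196 to 5.79 ± 0.471 RPKM and from 5.88 ± 0.622 to 14.5 ± 1.00 RPKM. Of 8 integrated stress response genes 5 rose and 1 fell, with 5 and 2 adjusted over the list alone. This list did not pass (camera adjusted p = 0.376, and adjusted p = 0.760 with an estimated correlation). Of 15 endoplasmic reticulum chaperones 3 rose and 2 fell, with the same counts adjusted over the list alone. Rises and falls numbered 8 and 1 with the library total alone and 2 and 5 with the listed-gene sum. The chaperone list did not pass either (camera adjusted p = 0.662, and adjusted p = 0.899 with an estimated correlation). Errors are SD with n = 4. In all, 12 of 29 lists passed with camera's preset correlation and 0 with an estimated correlation. Of the 35 splits of the 8 libraries into 4 and 4, 11 gave at least 12 lists, the real split included. The number of lists therefore does not stand apart from these splits. The other splits mix the genotypes. Those that mix them unevenly keep part of the genotype difference, so they do not show what chance alone gives.

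**Figure D2:**
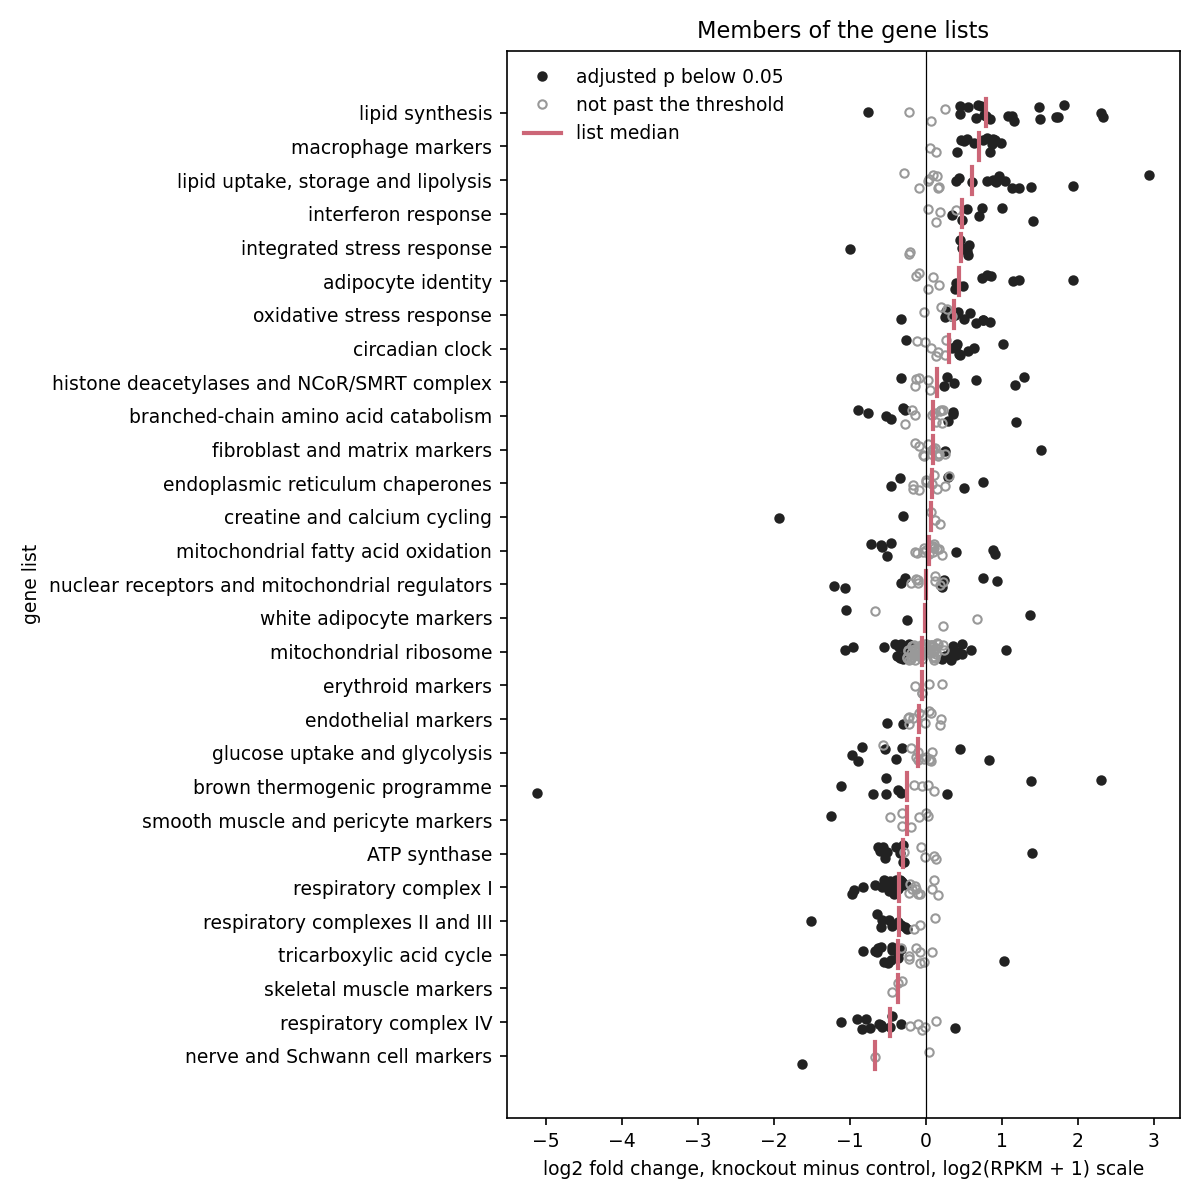
Log2 fold change (knockout minus control, on the log2(RPKM + 1) scale) of each tested member of the 29 gene lists, with filled points for members past the adjusted threshold of 0.05, open points for the others and a red bar at each list's median. Lipid synthesis has the highest median, 0.79, and complex IV a median of -0.48.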

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

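The tests of scaling, adipocyte share, cell types moving alike, unequal rises of macrophage markers and Rn45s were chosen after the results were seen. Within each genotype, 8 of 278 groups of 4 libraries had a library far from the other 3, where chance gives about 13.9. Pm20d1 stood at 0.603 RPKM in knockout replicate 5, against 0.398 to 0.423 in the others. Tst stood at 2.55 RPKM in control replicate 11 (others 3.73 to 3.93). Ifit3 stood at 5.80 RPKM in knockout replicate 5 (others 3.76 to 3.86). Tyms stood at 1.93 RPKM in knockout replicate 4 (others 3.17 to 3.31). Igfbp3 stood at 1.18 RPKM in control replicate 14 (others 1.52 to 1.56). Rgs5 stood at 43.2 RPKM in control replicate 11 (others 37.4 to 38.1). Myh11 stood at 1.17 RPKM in knockout replicate 4 (others 2.16 to 2.32). Mybpc2 stood at 2.80 RPKM in knockout replicate 5 (others 0.218 to 0.541).

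Other splits of the libraries were used to ask whether chance can be excluded. For genes higher in knockout, 1 of 35 splits (the real one) gave as many as 1703, and the highest other count in either direction was 2. For genes lower in knockout, 1 of 35 gave as many as 1391, again with a highest other count of 2. This argues against chance for both counts but does not exclude it, since 1 of 35 is the smallest share these splits can give. All other splits put both genotypes in each group, which widens the spread there and lowers their counts. The splits also cannot tell genotype apart from anything else that parts the same libraries. For gene lists past the threshold, 11 of 35 splits gave at least the real 12, and the highest other split gave 17. Splits that mix the genotypes unevenly keep part of the genotype difference. The comparison of list counts therefore neither excludes chance nor shows it. Camera's preset correlation is far below the correlation estimated for complex I, 0.556. In a check added after this was seen, the size of the median log2 fold change was largest in the real split for 15 of 29 lists, including all 12 lists past the threshold. Those 12 lists were picked for their shift in the real split, and the other splits keep at most part of the genotype difference. Their rank was therefore largely fixed in advance and adds no support for the lists.

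Respiratory chain and tricarboxylic acid cycle transcripts were lower, with a median log2 fold change of -0.36 over 101 genes. Scaling alone is argued against, since the median with the library total alone was still negative, at -0.18 (95% bootstrap interval over genes -0.26 to -0.13). The size of the fall depends on the scaling. The interval treats genes as independent and so understates the spread. Random lists matched on gene length, GC content and expression had medians of 0.08 to 0.21 (95% range), and 0% of 10000 reached the observed one. Genes of the respiratory chain and cycle lists move together (estimated correlation 0.43 to 0.68), while random lists hold unrelated genes. The 0% therefore overstates the certainty, though the matched medians lay on the other side of 0. A lower share of adipocytes is argued against by adipocyte identity genes, whose median was 0.44 (0.14 to 0.86), though these genes may themselves respond to Hdac3. This interval too treats genes as independent. The median rests in part on Cidec, Fabp4, Plin1 and Lipe, which rose and also belong to the lipid storage list. Adipoq, Cfd, Pck1, Acvr1c and Adipor2 rose as well. Pparg, Cebpa, Cebpb, Adig and Aqp7 did not pass, with log2 fold changes of -0.14 to 0.18, and none of the 14 genes passed as lower. An effect of Hdac3 loss in adipocytes is a hypothesis that stays open, with or without a different mix of adipocyte types.

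Macrophage markers were higher. A lower share of adipocytes would raise every other cell type alike, yet the macrophage median exceeded the endothelial one by 0.78 (0.50 to 1.05). This interval leaves out the correlation between genes, estimated at 0.25 within macrophage and 0.22 within endothelial markers. More macrophages with unchanged expression per cell, as the only change, would raise the 14 markers by a common fold if macrophages alone made them. Whether other cells in the tissue made some of them was not tested, so unequal folds would not exclude this explanation. Their log2 fold changes on the voom scale ranged from 0.10 to 1.27. The 35 splits do not decide whether this is more unequal than a common fold allows (exact permutation test, p = 0.114). The other splits mix the genotypes, so the genotype difference enters their spread. A chi-square approximation run first gave p = 0.000185; it was replaced by the exact permutation test because it ignores the correlation between genes and the small number of libraries. More macrophages and changed expression per cell cannot be told apart, as bulk tissue gives no count of cells.

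The share of reads on listed genes was larger in the knockout. A few abundant genes are argued against as the whole cause: without the 100 most abundant genes the lowest knockout library still lay 0.522 percentage points above the highest control library. With them it lay 1.283 percentage points above. The group means were 18.3% in control and 23.2% in knockout libraries with these genes and 13.9% and 16.6% without them, so these genes carry a large part of the difference. Ribosomal RNA left after depletion cannot be told apart from other sources of unlisted reads. Rn45s took 0.0722% of reads in control and 0.0542% in knockout libraries, with overlapping ranges (exact permutation test, two-sided p = 0.143), and reads outside the listed genes were not analysed here.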

How the results depend on the processing

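The sum of reads on listed genes was added as a scaling after the data were seen. The planned count tests of edgeR and DESeq2 were not run. For RPKM the plan named a count test on recovered whole reads as an added alternative. Limma voom was run on the recovered reads instead. The counts of 1703 genes higher and 1391 lower became 2796 and 628 with the library total alone, and 1087 and 2651 with the listed-gene sum, which follows from the shift of all genes. Requiring a log2 fold change of at least 1 left 178 higher and 69 lower. All other settings kept both counts within 1.5 times: leaving out a library gave 1439 to 1547 higher and 1162 to 1300 lower, and Hdac3 log2 fold changes of -1.09 to -0.95. No gene called in the main test was called in the opposite direction under any scaling, filter, pseudocount, voom or left-out library. Hdac3 passed in all of them. The 12 lists past the threshold became 0 with an estimated correlation and 18 with fry, and leaving out a library gave 12 or 13. Lists called lower by fry but not called in the main result were the brown thermogenic programme, glucose uptake and glycolysis, and creatine and calcium cycling. Smooth muscle and pericyte markers and nerve and Schwann cell markers were also called lower by fry. It called the histone deacetylases and NCoR/SMRT complex higher.

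Direction changed only for genes and lists that did not pass in the main result. The log2 RPKM difference moved by 0.18 with the library total alone and by -0.16 with the listed-gene sum. Under these scalings the turns of single genes and of medians follow from that shift. The cause of the other turns was not tested. For lists, the direction of the test and the sign of the median can change apart. With the library total alone Hbb-b1 was 0.031 and Hba-a2 0.13. The medians that turned were those of the mitochondrial ribosome (-0.05 to 0.12), glucose uptake and glycolysis (-0.11 to 0.07), white adipocyte (-0.01 to 0.08), endothelial (-0.09 to 0.07) and erythroid markers (-0.05 to 0.13). The test, not the median, turned for mitochondrial fatty acid oxidation (median 0.22) and nuclear receptors and mitochondrial regulators (0.14). With the listed-gene sum Esrra was -0.038, Pcna -0.13, Mbp -0.077 and Alas2 -0.089. The medians that turned were those of fatty acid oxidation (-0.11), branched-chain amino acid catabolism (-0.06), creatine and calcium cycling (-0.03), nuclear receptors (-0.13), endoplasmic reticulum chaperones (-0.06) and fibroblast markers (-0.06). The test, not the median, turned for white adipocyte (-0.098) and erythroid markers (-0.21).

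The test of mitochondrial fatty acid oxidation also turned without a filter and with fry (median 0.046 in both). The median of nuclear receptors and mitochondrial regulators, 0.0026 in the main result, turned with RLE factors (-0.0048), a pseudocount of 0.1 (-0.0086) and voom (-0.0094, where the test turned too). Leaving out a library gave -0.035 to 0.035 for Pcna, -0.078 to 0.14 for Mbp, -0.0029 to 0.41 for Hbb-b2, -0.27 to 0.013 for Hbb-b1, -0.086 to 0.11 for Alas2 and -0.17 to 0.11 for Hba-a2. It gave list medians of 0.0054 to 0.090 for mitochondrial fatty acid oxidation and 0.030 to 0.14 for branched-chain amino acid catabolism, where only the test turned. Medians ran from -0.027 to 0.063 for nuclear receptors and mitochondrial regulators, -0.24 to 0.057 for white adipocyte markers and -0.17 to 0.11 for erythroid markers; that of creatine and calcium cycling was -0.04 without knockout replicate 4. Glucose uptake and glycolysis (adjusted p = 0.0503) passed under several settings, with the library total alone among them, where its median and its test differed in sign.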

Other observations

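The lists in this part, and the genes named from them, were chosen after their values had been seen, so their tests describe the same data. Of 21 genes of peroxisomal fatty acid oxidation tested, 14 rose and 2 fell in the knockout (camera adjusted p = 0.000227 over 5 such lists; adjusted p = 0.145 with an estimated correlation). Slc25a17, a peroxisomal carrier, rose from 5.92 to 13.3 RPKM, and Phyh, which starts the breakdown of branched fatty acids, fell from 140 to 72.3 RPKM. All 16 tested genes of antigen presentation rose (camera adjusted p = 3.94e-08; adjusted p = 0.145 with an estimated correlation). Psmb8, an immunoproteasome subunit, rose from 6.14 to 21.2 RPKM, and B2m, the light chain of class I molecules, from 163 to 288.1 RPKM. Macrophage markers rose in the same libraries. Of 13 genes of cholesterol synthesis 5 rose and none fell (camera adjusted p = 0.00889; adjusted p = 0.145 with an estimated correlation), and Insig1, a sterol sensor, rose from 17.2 to 72.4 RPKM.

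Of 29 replication-dependent histone genes tested, 16 fell and none rose (camera adjusted p = 7.28e-06; adjusted p = 0.145 with an estimated correlation). Hist1h3e went from 10.7 to 2.80 RPKM. Of 60 small nucleolar RNAs tested, 20 rose and 1 fell (camera adjusted p = 0.00154; adjusted p = 0.181 with an estimated correlation). The one that fell was Scarna2, from 47.2 to 9.50 RPKM. These RNAs are short or lack a poly(A) tail and share sequence within families. Their values may therefore depend on how the RNA was prepared and how reads were counted. No explanation was tested for these lists.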
